A study of Mus musculus with 8 samples.

How the data were processed

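Gene expression was measured in tissue that the labels give as the rear part of the palate of newborn BALB/c mice on postnatal day 1. The dams had carried an osmotic minipump, a device under the skin that releases fluid at a steady rate, filled with saline or with nicotine at 1.5, 3.0 or 4.5 mg/kg/day. Each of the 4 groups had 2 arrays, which the labels call biological replicates. Whether an array held RNA of 1 pup or of several, and from how many litters, is not given in the sources used here, so the p-values measure the spread between the samples.

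The deposited values are in the unit intensity: linear summaries made by the authors for 45101 probe sets on each of 8 Affymetrix arrays. How the authors summarized, background-corrected and scaled them is not given in the sources used here. The median intensity per array lay between 20.7 and 25.4 and the mean between 121 and 139. The lowest value per array lay between 0.79 and 1 and the highest between 6687 and 19254. No column of values was left unused. The number of arrays limits the precision of every value.

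Of the probe sets, 34958 named 1 gene, 932 named several, 9147 named none and 64 were controls. Gene symbols came from the platform annotation, and 34754 of the probe sets with 1 gene were matched to the reference gene table by Entrez ID. The values were taken as log2(intensity + 16). The added 16 shrinks the fold changes of genes near background, so that a fold against a group at background is understated. Array medians on this scale differed by 0.17, more than the limit of 0.1 set for this case, and the 8 arrays were therefore brought to the same distribution by quantile normalization. Each of 18194 genes was represented by its probe set with the highest mean level. Genes under the 40th percentile of all probe sets (a log2 level of 4.94) were left out, and 13592 genes were tested, 74.7% of the genes with a probe set.

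Group means were fitted over all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual and 6.85 total degrees of freedom. Each nicotine dose, and the mean of the 3 doses, was compared with saline, and the doses were compared with each other. A slope of log2 level per mg/kg/day was fitted over the doses 0, 1.5, 3.0 and 4.5, and an F test asked for any difference among the groups. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were counted as changed, with no fold minimum. Errors of fold changes are standard errors of the fit.

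For the lists, 33 groups of genes (786 genes) were fixed, and 32 of them with 5 or more tested genes were tested with camera, which compares the genes of a list with all other genes, at its preset correlation of 0.01. The list of sex-linked genes was read per array only. P-values of the lists were adjusted over 128 tests, 32 in each of 4 comparisons. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move without comparing them with other genes, were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone. A further 16 lists of textbook markers for organs, teeth, orofacial patterning and Hox genes were written after gene values had been seen, and are given as levels per array without a test of the list, their members above the level filter being tested as single genes with all others.

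The genes named are, for each dose, the 10 with the largest rise and the 10 with the largest fall among changed genes whose 2 treated arrays lay on the same side of both saline arrays. For the trend and between doses they are the 5 of each direction with the smallest p, and the same choice, made after the data were seen, was used for the mean of the doses. For each list they are up to 4 members with the smallest p. A further 14 genes of palate formation, nicotinic signalling and nicotine metabolism are given whatever their result, except 1 that is not reported here. A named gene outside these choices is said to be so where it appears. Of 84 genes named by the choices per comparison and the fixed 14, 43 had more than 1 probe set above the level filter. In 10 of these the probe sets above the filter differed in direction (Kcnq1ot1, Trbv1, Tmed5, Slc4a4, Pabpn1, Mmd, Nabp1, Cgn, Trp63 and Shh). Probe sets below the filter were not compared.

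The procedure was tested on simulated data with 10 runs. At a 4-fold change it recovered 78.5% to 82.1% of changed genes in a dose comparison and 92.0% for the mean of the doses. At a 2-fold change it recovered 6.12% to 7.76% and 34.8%, and at 1.5-fold at most 1.19%. Between 4.27% and 6.50% of its calls were false. All 10 simulated lists of 20 genes shifted by 0.5 log2 units were found in each comparison, and at most 1 of 300 unchanged lists was called. The simulated noise was independent between genes, so these runs do not test lists whose genes move together. In the real data the correlation estimated for skeletal muscle fibre was 0.71.

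The groups, tests, gene lists, named-gene choices and most alternatives were fixed before the data were examined. The alternatives were an added constant of 1 or 64, values as deposited, centring each array on its median, no level filter or one at the 60th percentile, the mean of a gene's probe sets, eBayes with trend and robust, array weights, replicate number as a block, a fold minimum of 1.5, fitting only the 4 arrays of a comparison, and leaving out each array in turn. Chosen after the data were seen were leaving out both arrays of nicotine 1.5 and leaving out the 2 arrays highest in liver genes, and the camera test between doses. Overlap between dose comparisons was set beside 50 simulations in which no group differed. In each, the comparisons shared 2 simulated saline arrays, as the real comparisons share theirs, and the noise was independent between genes. Figures were drawn with matplotlib 3.10.9.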

Results

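Gene expression was read on 8 Affymetrix arrays in tissue labelled as palate from newborn mice whose dams received saline or nicotine at 1.5, 3.0 or 4.5 mg/kg/day, with 2 arrays in each of the 4 groups. Median intensities per array lay between 20.7 and 25.4. Across genes, which are not independent replicates, the log2 levels of the 2 arrays of a group correlated at r = 0.891 in saline, 0.898 at nicotine 1.5, 0.982 at 3.0 and 0.954 at 4.5. The first principal component held 50.3% of the variance and placed saline replicates 1 and 2 at -54.7 and -79.7, with the nicotine arrays between -0.03 and 35.9. The second held 18.9% and set nicotine 1.5 replicate 1 apart at 51.7. Eif2s3y, a gene of the Y chromosome, had an intensity of 301 in saline replicate 1 and 236 in nicotine 3.0 replicate 1 and at most 6.86 elsewhere. Xist, the RNA of the inactive X chromosome, was at 2.1 and 3.61 in these 2 arrays and at 447 to 1233 in the other 6. The ratio of 3' to 5' actin signal, a sign of RNA integrity, was 1.70 ± 0.07 (SD, n = 2) in saline, 1.29 ± 0.13 at nicotine 1.5, 1.10 ± 0.06 at 3.0 and 1.05 ± 0.14 at 4.5. The Gapdh ratio was 1.27 ± 0.06, 1.11 ± 0.05, 0.97 ± 0.02 and 0.98 ± 0.10 in the same order.

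Genes typical of internal organs stood far above background in some arrays and at background in others. The median log2 level of 15 stomach genes was 7.86 and 7.66 in saline replicates 1 and 2 and 4.44 to 4.77 in the 6 nicotine arrays. That of 21 intestine genes was 9.62 and 7.69 against 4.57 to 5.14. Liver genes (20) had medians of 7.82 and 11.27 in the saline arrays and 9.11 in nicotine 1.5 replicate 2, and of 4.46 to 4.72 in the other 5 arrays. Albumin (Alb), the main plasma protein, was at 11.80, 12.80 and 12.29 in those 3 arrays and at most 5.44 elsewhere. Kidney genes (10) reached 8.53 in saline replicate 2 and 4.53 to 5.22 in the other arrays. Lung genes (12) had medians of 9.37 in nicotine 1.5 replicate 2, 9.58 and 7.30 in nicotine 3.0 replicates 1 and 2, and 6.45 and 6.71 in nicotine 4.5, against 4.69 to 4.81 in the saline arrays and nicotine 1.5 replicate 1. Heart genes (14) were at 8.51 in nicotine 1.5 replicate 2 and at most 5.64 elsewhere. Genes of brown fat (11), the heat-producing fat of the neck and trunk, had medians of 5.13 to 5.24 in saline and nicotine 1.5 replicate 1 and of 6.44 to 8.47 in the other 5 arrays. Visceral smooth muscle genes (9) went from 8.27 and 7.93 in saline to 5.76 and 5.60 at nicotine 4.5. Thymus genes (11) were at 4.98 and 5.0 in the nicotine 4.5 arrays and at most 4.39 elsewhere. The medians of pancreas (10), brain (14) and thyroid genes (4) stayed between 4.33 and 5.66 in all 8 arrays, although 7 of the 14 brain genes exceeded 5.73, the 60th percentile of all probe sets, in saline replicate 1, against 1 to 3 elsewhere.

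Tooth genes and genes that pattern the face and jaws were near background, while the 32 genes of the palate and cleft list that had passed the level filter had medians of 6.44 to 7.51. Tooth genes (8) had medians of 4.36 to 4.66. In no array did any of them exceed 5.73. Genes that pattern the face and jaws (12) had medians of 4.73 to 5.07, with at most 3 members above 5.73 in an array. Hox genes, which are expressed along the body axis behind the head, were measured in the same way. The 12 genes of groups 4 to 8 had medians of 5.67 to 6.31. The 14 genes of groups 9 to 13 had 2 to 7 members above 5.73 in every array. Their medians were 5.36, 6.08 and 5.49 in saline replicates 1 and 2 and nicotine 1.5 replicate 1. In the other 5 arrays they were 4.71 to 4.89, no higher than the range of the face and jaw genes there, 4.76 to 5.07. Hoxc10, a Hox gene of the lower trunk and hindlimb, was at 7.30, 6.56 and 7.84 in the saline arrays and nicotine 1.5 replicate 1 and at 4.23 to 4.80 in the other 5.

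**Figure D1:**
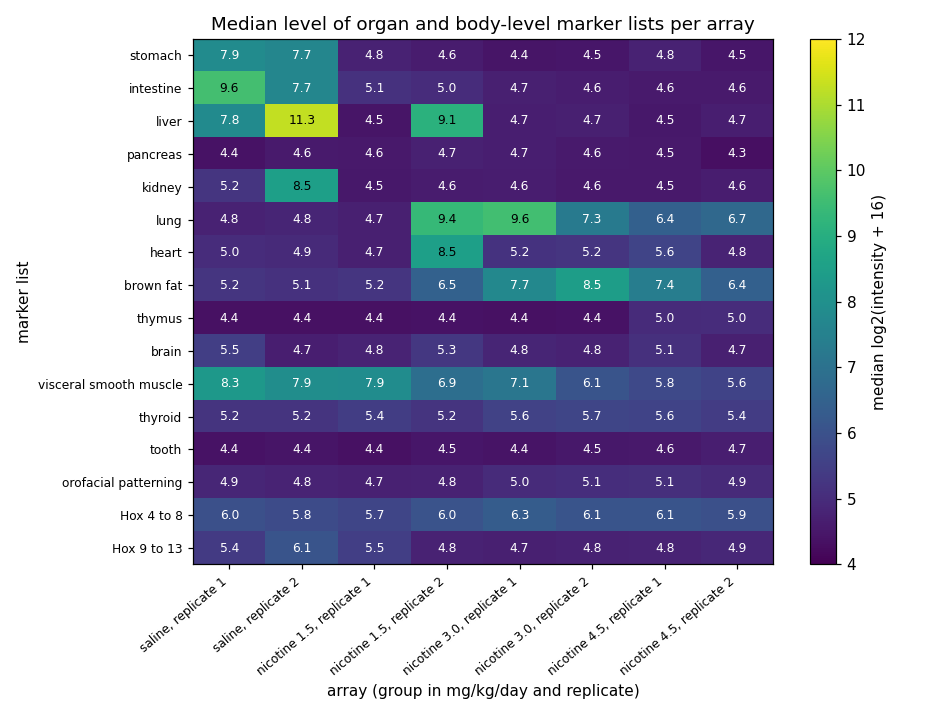
Median log2(intensity + 16) of each marker list (vertical axis) in each of the 8 arrays (horizontal axis), shown by colour and printed in each cell. Stomach genes are at 7.86 and 7.66 in the saline arrays and at most 4.77 in the others, and tooth genes stay at or below 4.66 in all arrays.

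The mean of the 3 nicotine doses was compared with saline to ask what differed between them on average over the doses. Stomach gene medians and the actin 3' to 5' ratio differed between the same groups, as given above. Unless said otherwise, a change against saline therefore cannot be told apart from a difference in tissue makeup or RNA integrity. Cym, the milk-clotting protease of the newborn stomach, fell by 7.79 ± 0.13 log2 units (SE; adjusted p = 2.34e-06), from intensities of 5168 and 5000 in the saline arrays to 5.2 to 11.87 in the nicotine arrays. Mymk, which fuses myoblasts into muscle fibres, rose by 1.86 ± 0.16 (adjusted p = 0.00153). Of 13592 genes tested, 1380 changed, 646 higher and 734 lower.

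Among the falls with the smallest p in that comparison were Apoa4, an apolipoprotein of the intestine, at -6.57 ± 0.20, Pga5, a pepsinogen of the stomach, at -5.90 ± 0.21, Gkn2, a gastrokine of the stomach lining, at -4.55 ± 0.16, and Clps, the colipase that helps to digest fat, at -4.49 ± 0.13 (adjusted p from 2.95e-05 to 5.36e-05). Among the rises with the smallest p were Ryr1, the calcium release channel of muscle, at 1.62 ± 0.18, Cacna1s, its voltage sensor, at 1.61 ± 0.18, Sgca, a sarcoglycan of the muscle membrane, at 1.72 ± 0.20, and Mief2, a factor of mitochondrial fission, at 1.23 ± 0.13 (adjusted p from 0.00390 to 0.00538).

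Muscle lists were tested in this comparison too. All 36 genes of skeletal muscle fibres had a positive fold change, with a median of 0.93 (camera adjusted p = 6.36e-11, and adjusted p = 0.815 with an estimated correlation). By fry, in a single direction, the list did not pass either (adjusted p = 0.0847). Of these 16 rose, 26 when adjusted over the list alone, among them Myoz1, a protein of the Z-disc, at 1.25 ± 0.16 and Pygm, the glycogen phosphorylase of muscle, at 1.78 ± 0.24. The 15 myogenic regulators had a median of 1.04 (camera adjusted p = 6.56e-06, adjusted p = 0.815 with an estimated correlation, and fry adjusted p = 0.0596). Here 3 rose, 11 when adjusted over the list alone: Mymk, Itga7, a laminin receptor of muscle, at 1.25 ± 0.15, and Cdh15, a cadherin of muscle precursors, at 1.21 ± 0.14. The 17 nicotinic and cholinergic genes had a median of 0.70 and 5 rose, 9 when adjusted over the list alone (camera adjusted p = 0.00300, and 0.439 as the adjusted p with an estimated correlation). Those with the smallest p were Chrnb1 at 1.19 ± 0.14, Chrng at 1.38 ± 0.23 and Chrnd at 0.64 ± 0.13, subunits of the receptor of muscle, and Rapsn, which clusters it, at 0.98 ± 0.15. Stomach gene medians in the same groups went from 7.76 ± 0.15 (SD, n = 2) in saline to 4.69 ± 0.12, 4.46 ± 0.03 and 4.62 ± 0.19, and the actin 3' to 5' ratio from 1.70 to 1.05.

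Other lists moved in both directions. Genes of oxidative stress and NRF2, the main regulator of antioxidant genes, fell, with a median of -0.67 over 24 genes; 7 fell, 13 when adjusted over the list alone (camera adjusted p = 3.45e-07, and 0.439 as the adjusted p with an estimated correlation). Nqo1, a quinone reductase, changed by -3.32 ± 0.21, Gsta2, a glutathione transferase, by -3.74 ± 0.58, Gpx2, the glutathione peroxidase of the gut lining, by -1.89 ± 0.27, and Gclc, which makes glutathione, by -1.13 ± 0.21. Of 10 genes of salivary and mucous glands 5 fell, also when adjusted over the list alone, where 2 rose; the median was -1.61 (camera adjusted p = 0.00242, and 0.802 as the adjusted p with an estimated correlation). Bpifb1, a secreted protein of mucosal surfaces, was at -5.29 ± 0.19, the mucin Muc5b at -3.88 ± 0.28, and Tff2, a trefoil peptide of the stomach, at -2.33 ± 0.25. Pigr, which carries antibodies across epithelia, was at -1.05 ± 0.18. Epithelial adhesion genes fell, 6 of 27 singly and 7 when adjusted over the list alone (median -0.22; camera adjusted p = 0.00834, and adjusted p = 0.815 with an estimated correlation), among them Epcam, an adhesion molecule of epithelia, at -3.45 ± 0.45, and Cldn7, a claudin of tight junctions, at -3.09 ± 0.44. Lists of the cell cycle (median -0.48, 2 of 33 fell and 0 when adjusted over the list alone, camera adjusted p = 4.13e-05) and the interferon response (median -0.39, 3 of 19 fell and 6 when adjusted over the list alone, camera adjusted p = 0.00685) also fell. For these last 2 lists adjusted p = 0.815 with an estimated correlation. At 1.5 mg/kg/day alone epithelial adhesion and the cell cycle did not pass, with medians of 0.26 and 0.01 (adjusted p = 0.825 and 0.5003). Intestine genes, rich in epithelium, went from a median of 8.65 ± 1.36 (SD, n = 2) in saline to 4.58 ± 0.01 at nicotine 4.5.

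Lists that rose beside muscle with the mean of the doses were adipocyte (median 1.63; 5 of 19 rose and 1 fell, 9 and 1 when adjusted over the list alone), mitochondrial respiration (0.67; 6 of 23, 9 over the list alone), endothelium (0.68; 4 of 21 rose and 1 fell, with the same counts over the list alone), collagen and matrix (0.61; 0 of 29 singly), osteoblast and bone (0.45; 2 of 13, 4 over the list alone), TGF-beta signalling (0.35; 2 of 28, 7 over the list alone) and glucocorticoid response (0.67; 3 of 18, 4 over the list alone). Their camera adjusted p lay between 3.73e-05 and 0.0490, and with an estimated correlation adjusted p = 0.815 for each. Cidea, a lipid droplet protein of brown fat, rose by 3.72 ± 0.45 and Cox8b, a cytochrome oxidase subunit, by 2.69 ± 0.39. Pecam1, an adhesion molecule of endothelium, rose by 1.08 ± 0.21, and Col22a1, a collagen of tissue junctions, by 1.56 ± 0.27. Brown fat gene medians were 5.18 ± 0.07 (SD, n = 2) in saline, 5.86 ± 0.88, 8.09 ± 0.53 and 6.91 ± 0.67 in the nicotine groups. Of the 12 brown fat genes 4 stand in other lists too, Ucp1 and Cidea in adipocyte, Cox7a1 in mitochondrial respiration and Lhx8 in palate and cleft genes. These readings are therefore not separate.

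Among the genes chosen for their part in palate formation, Tgfb3, needed for fusion of the palatal shelves, rose by 1.11 ± 0.24 with the mean of the doses (adjusted p = 0.0345), and Jag2, a Notch ligand, by 0.95 ± 0.18 (adjusted p = 0.0264). Cdh1, the main cadherin of epithelia, fell by 2.13 ± 0.35 (adjusted p = 0.0170), and Chrna1, a subunit of the muscle nicotinic receptor, rose by 1.34 ± 0.31 (adjusted p = 0.0410). Tgfbr2, the receptor of Tgfb3, stood at 0.69 ± 0.19 (adjusted p = 0.0660). Shh at -0.36 ± 0.33, Snai2 at -0.24 ± 0.22, Msx1 at 0.23 ± 0.18, Twist1 at 0.52 ± 0.45, Trp63 at 0.16 ± 0.51 and Chrna3 at 0.05 ± 0.17 did not pass (adjusted p from 0.432 to 0.857). Chrna7 was below the level filter, and Cyp2a5 had no probe set that named it alone, so it was not measured here. The palate and cleft list as a whole did not pass in this comparison (median over 32 genes 0.25, camera adjusted p = 0.291). In it 3 members rose and 1 fell, 6 and 1 when adjusted over the list alone, among them Meox2, a homeobox gene, at 1.54 ± 0.31, and Bmp2, a bone morphogenetic protein, at -1.19 ± 0.23. The fit without the 2 arrays highest in liver genes, saline replicate 2 and nicotine 1.5 replicate 2, left Tgfb3, Jag2 and Chrna1 short of the limit (adjusted p up to 0.105), as did leaving out saline replicate 2 or either array of nicotine 3.0 (up to 0.140), and for Tgfb3 and Chrna1 also either array of nicotine 4.5 and for Chrna1 either array of nicotine 1.5; nor did Cdh1 pass without either saline array (up to 0.0740). The count of 1380 became 355 and 366 without nicotine 3.0 replicates 1 and 2, 614 and 812 without nicotine 4.5 replicates 1 and 2, 655 without saline replicate 2 and 618 with array weights, and with values as deposited it was 1273, 346 higher and 927 lower. Without saline replicate 2 the calls for collagen and matrix, adipocyte, cell cycle, salivary and mucous gland, osteoblast and bone and TGF-beta signalling were lost, and without saline replicate 1 that for endothelium. Those for glucocorticoid response (kept in 13 of 20 alternatives), TGF-beta signalling (12) and osteoblast and bone (13) were the least stable. The first was lost without saline replicate 1, nicotine 1.5 replicate 2, nicotine 3.0 replicate 1 or nicotine 4.5 replicate 2, with an added constant of 1 and with arrays centred on their medians. TGF-beta signalling was also lost without nicotine 1.5 replicate 1, nicotine 3.0 replicate 1 or nicotine 4.5 replicate 2, and osteoblast and bone without replicate 1 of nicotine 1.5 or 4.5. The call for epithelial adhesion was lost without nicotine 1.5 replicate 2, that for salivary and mucous gland also with an added constant of 1 or no level filter, and that for the interferon response with the filter at the 60th percentile. Without the 2 arrays highest in liver genes, those for epithelial adhesion, collagen and matrix, adipocyte, cell cycle, salivary and mucous gland and TGF-beta signalling were lost.

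**Figure D2:**
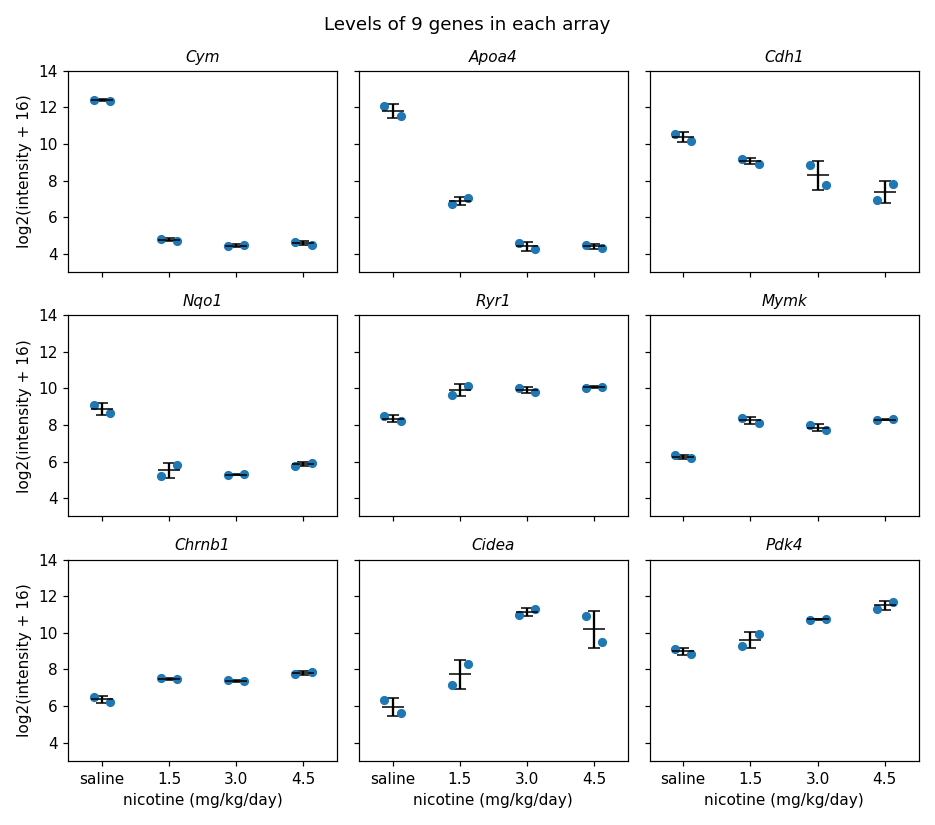
Levels of 9 genes, as log2(intensity + 16) on the vertical axis, against the nicotine dose; points are single arrays, and bars give the mean and SD of the 2 arrays of a group. Cym drops by 7.79 log2 units between saline and the mean of the doses, and Mymk lies 1.86 higher.

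Nicotine at 1.5 mg/kg/day, the lowest dose, was compared with saline next. Genes of muscle and of the stomach were among the largest changes that passed the test. Tnni1, the troponin I of slow muscle, rose by 2.03 ± 0.31, Mymk by 1.98 ± 0.19 and Mmp9, a gelatinase of bone-resorbing and migrating cells, by 2.04 ± 0.38 (adjusted p from 0.00612 to 0.0474). Cym fell by 7.62 ± 0.16 (adjusted p = 1.09e-05). In all 337 genes changed, 99 higher and 238 lower.

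The other large rises at 1.5 mg/kg/day lay between 1.72 and 1.87. They included Usp2, a deubiquitinase, at 1.87 ± 0.31, Mirg, an imprinted noncoding RNA, at 1.87 ± 0.24, and Kcnq1ot1, another, at 1.84 ± 0.30. Among them too were Dusp27, a muscle protein, at 1.80 ± 0.34, Tppp3, which binds tubulin, at 1.72 ± 0.30, Pygm at 1.72 ± 0.29, and Tmem38a, an ion channel of the muscle calcium store, at 1.72 ± 0.31. The other large falls lay between -6.17 and -4.53. They were those of Pga5, Fabp2, the fatty acid binding protein of the intestine, Bpifb1, Apoa4, Alpi, the alkaline phosphatase of the intestine, Fabp1, a fatty acid binding protein of liver and intestine, Clca4b, of a family that modulates chloride channels, Mttp, which loads lipid onto lipoproteins, and Leap2, a peptide of liver and intestine. Within the lists, skeletal muscle fibre rose with a median of 0.84 (5 of 36 genes, 17 when adjusted over the list alone; camera adjusted p = 6.78e-11), as did myogenic regulators (0.89; 3 of 15, 9 over the list alone; adjusted p = 6.29e-06). Both had an adjusted p = 0.815 with an estimated correlation. Nicotinic and cholinergic genes rose (0.59; 2 of 17, 3 over the list alone; camera adjusted p = 0.00263) and oxidative stress genes fell (-0.77; 1 of 24, 12 over the list alone; camera adjusted p = 9.90e-08). Each of these had an adjusted p = 0.439 with an estimated correlation.

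Cartilage and keratinized epithelium were high in 1 array of this dose. The 22 cartilage genes had a median of 1.88 (camera adjusted p = 0.00144, and adjusted p = 0.815 with an estimated correlation), with Col11a2, a cartilage collagen, at 2.31 ± 0.80 and Acan, the main proteoglycan of cartilage, at 2.34 ± 1.05. The 28 genes of keratinized epithelium had a median of 1.36 (camera adjusted p = 2.64e-04, and adjusted p = 0.815 with an estimated correlation), with Krt1, a keratin of the upper skin layers, at 3.61 ± 1.27 and Flg, a protein of the horny layer, at 3.28 ± 0.89. No member of either list passed singly or when adjusted over the list alone. Cartilage genes had a median level of 8.78 in replicate 1 and 5.36 in replicate 2, and keratinized epithelium 8.41 and 5.72. Without replicate 1 of this dose both calls were lost, and the median of the cartilage list turned to -0.05 (adjusted p = 0.965). Collagen and matrix (0.87, camera adjusted p = 8.88e-07; 0 of 29), TGF-beta signalling (0.49, adjusted p = 0.00341; 0 of 28, 3 over the list alone), osteoblast and bone (0.59, adjusted p = 0.00370; 0 of 13, 2 over the list alone) and EMT and mesenchymal genes (0.56, adjusted p = 0.0118; 2 of 20, 4 over the list alone) also rose. Adjusted p = 0.815 for these 4 with an estimated correlation. Further rises were those of palate and cleft genes (0.42, adjusted p = 0.0153; 0 of 32), Hedgehog signalling (0.51, adjusted p = 0.0263; 0 of 14) and endothelium (0.46, adjusted p = 0.0336; 0 of 21). An estimated correlation gave adjusted p = 0.815 for the first 2 and 0.853 for endothelium. Salivary and mucous gland (-1.49; 3 of 10 fell, 5 over the list alone with 1 rise) and the interferon response (-0.55; 1 of 19 fell, 6 over the list alone) fell, with camera adjusted p of 0.00261 and 0.00226. An estimated correlation gave adjusted p = 0.802 and 0.815. Ifit1, an interferon-induced protein, changed by -2.20 ± 0.40 and Zeb1, a repressor of epithelial genes, by 0.95 ± 0.17. Liver gene medians at this dose were 4.46 in replicate 1 and 9.11 in replicate 2, lung 4.69 and 9.37, and heart 4.70 and 8.51.

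For this dose the count of 337 became 912 without saline replicate 1, 155 without replicate 1 of the dose, 103 and 104 without the 2 arrays of nicotine 3.0, 133 without either array of nicotine 4.5, 157 with an added constant of 1, 128 with array weights and 15 with only the 4 arrays compared, and with values as deposited it was 262, 30 higher and 232 lower. Calls for palate and cleft genes, EMT and mesenchymal genes and Hedgehog signalling were lost without saline replicate 2 or without nicotine 1.5 replicate 1. Lost too were those for osteoblast and bone and interferon response without the latter, that for endothelium without saline replicate 1, nicotine 1.5 replicate 2 or the 2 arrays highest in liver genes, and that for salivary and mucous gland without saline replicate 2, with an added constant of 1 or with no level filter.

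At 3.0 mg/kg/day, genes expressed in brown fat were among the largest rises that passed the test. Cidea rose by 5.16 ± 0.55 (adjusted p = 0.00630), Otop1, a proton channel of brown fat, by 3.93 ± 0.71, Elovl3, a fatty acid elongase, by 3.20 ± 0.38 and Cox8b by 3.30 ± 0.48. Cym fell to background, by 7.93 ± 0.16 (adjusted p = 8.28e-06). The comparison gave 506 changed genes, 183 higher and 323 lower.

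The other large rises at 3.0 mg/kg/day were Cox7a1, a cytochrome oxidase subunit, at 3.44 ± 0.70, Rbp7, a retinol-binding protein of fat, at 3.36 ± 0.51, and the lipases Lipe at 3.19 ± 0.49 and Pnpla2 at 2.96 ± 0.44. Next came Oplah, an enzyme of glutathione turnover, at 2.86 ± 0.57, and Cyp4b1, a cytochrome P450, at 2.72 ± 0.46. Falls between -7.63 and -5.66 were those of Fabp1, Apoa4, Fabp2, Apoa1, the main protein of HDL, Cps1, the first enzyme of the urea cycle, Apoc2, which activates lipoprotein lipase, Rbp2, a retinol-binding protein of the intestine, Pga5 and Ugt2b34, a glucuronosyltransferase. The adipocyte list had a median of 2.12 over 19 genes (camera adjusted p = 5.26e-05, and adjusted p = 0.815 with an estimated correlation). In it 4 rose, 11 when adjusted over the list alone, among them Cidec, a lipid droplet protein, at 2.71 ± 0.38. Mitochondrial respiration had a median of 0.93, with all 23 genes positive and 5 past the test, 16 when adjusted over the list alone (camera adjusted p = 7.91e-08, and adjusted p = 0.815 with an estimated correlation). Idh3a, of the citrate cycle, was at 1.43 ± 0.27 and Ndufb5, of complex I, at 0.93 ± 0.18. Brown fat gene medians were 7.72 and 8.47 in the 2 arrays of this dose and 5.23 and 5.13 in saline. Ucp1, the uncoupling protein of brown fat, which is named here after its values were seen, was at 12.13 and 12.27 against 4.43 and 4.24. It did not pass the test at this dose. Lung gene medians were 9.58 and 7.30 in the arrays of this dose.

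Muscle lists rose at this dose too: skeletal muscle fibre with a median of 0.92 (6 of 36, 22 when adjusted over the list alone; camera adjusted p = 1.70e-10) and myogenic regulators with 1.0 (3 of 15, 6 over the list alone; adjusted p = 3.09e-05). So did endothelium (0.68; 1 of 21, 3 over the list alone; adjusted p = 0.00349), and with an estimated correlation adjusted p = 0.815 for the 3 lists. Sox18, a transcription factor of endothelium, was at 0.98 ± 0.17 and Ryr1 at 1.57 ± 0.22. Cell cycle genes fell, with a median of -0.84 and 32 of 33 negative, although 0 passed singly or when adjusted over the list alone (camera adjusted p = 9.78e-09, and adjusted p = 0.815 with an estimated correlation). Cdc20, an activator of mitotic exit, stood at -1.15 ± 0.24 (adjusted p = 0.0521). Epithelial adhesion fell (-0.44; 3 of 27, 7 over the list alone; camera adjusted p = 0.00233, and adjusted p = 0.815 with an estimated correlation), with Epcam at -3.63 ± 0.56, Cldn7 at -3.13 ± 0.54 and Dsc2, a desmosomal cadherin, at -2.92 ± 0.47. The interferon response fell too (-0.46; 1 of 19 fell, 4 over the list alone with 1 rise; adjusted p = 0.00547, and adjusted p = 0.815 with an estimated correlation). Nicotinic and cholinergic genes rose (0.65; 2 of 17, 7 over the list alone; camera adjusted p = 0.00495) and oxidative stress genes fell (-0.61; 5 of 24, 10 over the list alone with 1 rise; adjusted p = 4.76e-06), with Nqo1 at -3.59 ± 0.26. Both had an adjusted p = 0.439 with an estimated correlation. Salivary and mucous gland fell (-1.50; 4 of 10, 5 over the list alone with 1 rise; camera adjusted p = 0.00242) and collagen and matrix rose (0.45; 0 of 29; adjusted p = 0.0263). An estimated correlation gave adjusted p = 0.802 and 0.853. Stomach gene medians were 4.44 and 4.48 in the 2 arrays of this dose.

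At 3.0 mg/kg/day the count of 506 became 995 without saline replicate 1, 75 and 52 without replicates 1 and 2 of the dose, 262 and 261 without the arrays of nicotine 4.5, 294 with only the 4 arrays compared and 896 without the 2 arrays highest in liver genes, and with values as deposited it was 462, 99 higher and 363 lower. The call for collagen and matrix was lost, with the median at -0.03, without saline replicate 2, and was lost too without nicotine 3.0 replicate 1, without the 2 arrays highest in liver genes and with the mean of a gene's probe sets. That for salivary and mucous gland was lost without saline replicate 2, without the 2 liver-rich arrays, with an added constant of 1 and with no level filter, which also ended that for nicotinic and cholinergic genes.

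At the highest dose, 4.5 mg/kg/day, Cidea was among the rises that passed the test and Cym among the falls. In all 934 genes changed, 395 higher and 539 lower. Cidea rose by 4.23 ± 0.55, Pdk4, a kinase that spares glucose, by 2.53 ± 0.26 and Slc10a6, a transporter of steroid sulfates, by 3.21 ± 0.48 (adjusted p from 0.00488 to 0.0172). Cym fell by 7.82 ± 0.16 and Cdh1 changed by -2.99 ± 0.42 (adjusted p = 9.12e-06 and 0.0143).

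The further large rises at 4.5 mg/kg/day were Cox8b at 2.97 ± 0.48, Pnpla2 at 2.93 ± 0.44, Acacb, an acetyl-CoA carboxylase, at 2.87 ± 0.46, and Timp4, a metalloproteinase inhibitor, at 2.87 ± 0.65. Others were Mettl21e, a methyltransferase of muscle, at 2.87 ± 0.43, Zbtb16, a glucocorticoid-induced transcription factor, at 2.85 ± 0.62, Lipe at 2.83 ± 0.49, and Trbv1, a segment of the T cell receptor, at 2.68 ± 0.31. Further large falls, between -7.73 and -5.74, were those of Fabp1, Apoa4, Ttr, a carrier of thyroxine and retinol, Fabp2, Apoa1, Apoc2, Pga5, Cps1 and Rbp2. Thymus genes stood at 4.98 and 5.0 in the arrays of this dose and at 4.35 and 4.37 in saline.

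The glucocorticoid response list passed at 4.5 mg/kg/day and not at the other doses, with a median of 1.43 over 18 genes (camera adjusted p = 2.41e-04). Its median level was 9.82 and 9.93 in the arrays of this dose and 8.07 and 8.67 in saline. The arrays of nicotine 1.5 stood apart, at 8.06 and 9.43. In the list 6 rose, 11 when adjusted over the list alone, among them Cdkn1a, an inhibitor of the cell cycle, at 1.70 ± 0.18 and Per1, a clock gene, at 2.20 ± 0.36. With an estimated correlation adjusted p = 0.815 for the list. Skeletal muscle fibre rose with a median of 0.99 (11 of 36, 24 when adjusted over the list alone; camera adjusted p = 1.70e-10) and myogenic regulators with 1.11 (3 of 15, 9 over the list alone; adjusted p = 1.27e-05), each with an adjusted p = 0.815 with an estimated correlation. Also higher were adipocyte with 1.61 (4 of 19, 7 over the list alone; adjusted p = 0.00300), mitochondrial respiration with 0.78 (3 of 23, 8 over the list alone; adjusted p = 3.09e-05) and endothelium with 0.76 (2 of 21, 4 over the list alone with 1 fall; adjusted p = 0.00263). Adjusted p = 0.815 for each of these 3 with an estimated correlation. Brown fat gene medians were 7.39 and 6.44 in the arrays of this dose, and Ucp1 was at 11.89 in replicate 1 and 6.65 in replicate 2. Epithelial adhesion fell with a median of -0.53 (7 of 27, 8 over the list alone; camera adjusted p = 6.54e-05, and adjusted p = 0.815 with an estimated correlation), with Epcam at -3.98 ± 0.56, Cldn7 at -3.72 ± 0.54 and Ocln, of tight junctions, at -2.88 ± 0.46. The cell cycle list fell with -0.54 (1 of 33, 7 over the list alone; adjusted p = 6.43e-05, and adjusted p = 0.815 with an estimated correlation), with Mcm4, of the replication helicase, at -1.43 ± 0.26. Nicotinic and cholinergic genes rose (0.68; 4 of 17, 6 over the list alone with 1 fall; camera adjusted p = 0.00409), with Chrnb1 at 1.44 ± 0.18, Chrng at 1.62 ± 0.28, Rapsn at 1.10 ± 0.18 and Chrnd at 0.72 ± 0.16. Oxidative stress genes fell (-0.69; 4 of 24, 10 over the list alone; adjusted p = 6.56e-06), and for both lists adjusted p = 0.439 with an estimated correlation. Salivary and mucous gland fell (-1.83; 5 of 10, 5 over the list alone; camera adjusted p = 0.00139) and collagen and matrix rose (0.49; 0 of 29; adjusted p = 0.0105). An estimated correlation gave adjusted p = 0.802 and 0.853. Intestine gene medians were 4.57 and 4.58 in the arrays of this dose and 9.62 and 7.69 in saline.

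For 4.5 mg/kg/day the count of 934 became 190 and 154 without replicates 1 and 2 of the dose, 275 and 283 without the arrays of nicotine 3.0, 599 without saline replicate 2, 441 with array weights, where 3.0 mg/kg/day gave 715, and 316 with only the 4 arrays compared, and with values as deposited it was 942, 206 higher and 736 lower. Calls were lost for adipocyte without nicotine 4.5 replicate 1, for cell cycle without saline replicate 2 or nicotine 4.5 replicate 2 and for collagen and matrix and for salivary and mucous gland without saline replicate 2, and these last 3 also without the 2 arrays highest in liver genes. Trbv1 turned to -0.28 without nicotine 4.5 replicate 2, where another of its probe sets was the highest.

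**Figure D3:**
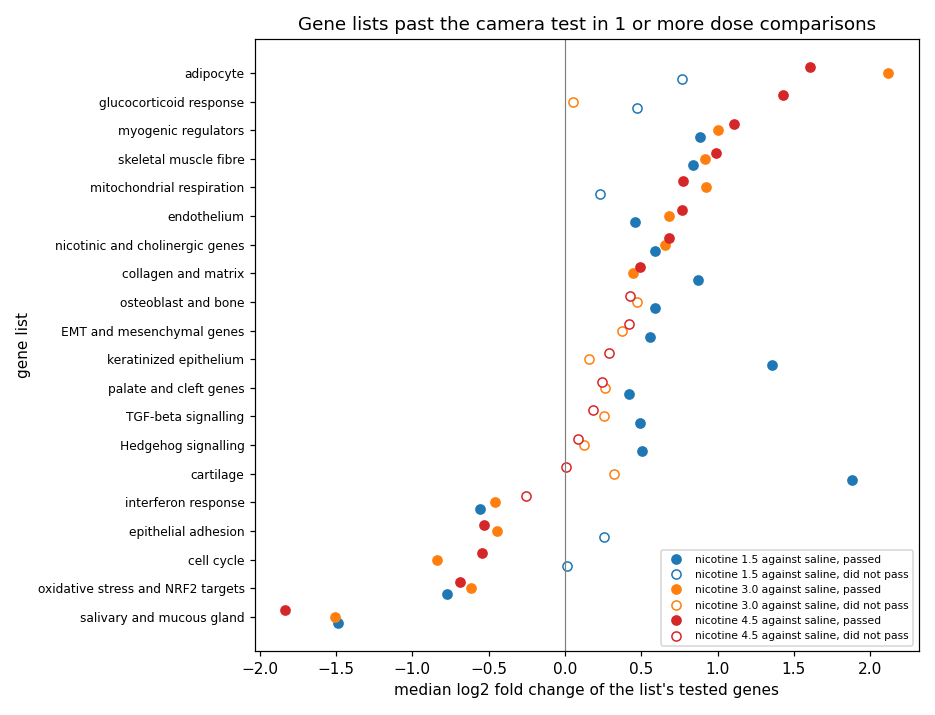
Median log2 fold change against saline (horizontal axis) of each gene list that passed the camera test in 1 or more dose comparisons (vertical axis), by dose; filled points passed at the preset correlation and open points did not. Skeletal muscle fibre lies at 0.84, 0.92 and 0.99 for nicotine 1.5, 3.0 and 4.5, and none of the lists passed with an estimated correlation.

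Whether the doses changed the same genes, and whether they differed, was asked directly. Cym, Apoa4, Fabp2, Fabp1 and Pga5 were among the 10 largest falls at every dose. Of changed genes, 238 were shared in direction between 1.5 and 3.0, 297 between 1.5 and 4.5 and 437 between 3.0 and 4.5 mg/kg/day, with 0 in opposite directions. In all, 236 were shared by all 3 doses (43 higher, 193 lower). Independent lists would share 1.33, 2.88 and 5.32 rises and 5.66, 9.44 and 12.8 falls. Simulated unchanged groups, compared with the same 2 simulated saline arrays, shared 0. Fold changes of the pairs of doses correlated across genes at 0.80, 0.86 and 0.93, against 0.50 in the simulations. Their covariance was 0.48, 0.54 and 0.69 against 0.06. Noise in the simulations was independent between genes, so a difference that many genes of the real saline arrays share was not modelled. The simulations therefore cannot tell a change common to the doses from one carried by the saline arrays. Without nicotine 3.0 replicate 2 the shared counts became 50, 103 and 51, and without nicotine 3.0 replicate 1 they became 68, 102 and 73. Without saline replicate 1 they became 659, 787 and 887. Without nicotine 4.5 replicates 1 and 2 they became 119 and 118, 114 and 101, and 132 for either. Without nicotine 1.5 replicates 1 and 2 the count for 1.5 and 4.5 became 139 and 184, that for 1.5 and 3.0 becoming 131 without replicate 1.

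Between the doses no gene passed the test in limma. At an unadjusted p under 0.05 there were 1472 genes for 3.0 against 1.5 mg/kg/day, 963 for 4.5 against 1.5 and 536 for 4.5 against 3.0, with smallest adjusted p of 0.163, 0.319 and 0.731. The smallest p for 3.0 against 1.5 belonged to Apoa4 at -2.45 ± 0.25, Pabpn1, which binds poly(A) tails, at -1.45 ± 0.17, Abhd15, a fat cell hydrolase, at 1.58 ± 0.15, Hoxa4, a Hox gene, at 1.64 ± 0.20, Elovl3 at 3.11 ± 0.38 and Tmed5, of vesicle transport, at 1.61 ± 0.20. Those for 4.5 against 3.0 belonged to Trbv1 at 2.75 ± 0.31, Elovl3 at -2.81 ± 0.38 and Mmd, a membrane protein, at -1.82 ± 0.25. Those for 4.5 against 1.5 belonged to Apoa4 at -2.47 ± 0.25, Trbv1 at 2.57 ± 0.31, Pdk4 at 1.90 ± 0.26, Pabpn1 at -1.31 ± 0.17 and Dsp, the desmosomal protein desmoplakin, at -3.38 ± 0.53. Some genes passed for 3.0 and 4.5 against 1.5 without the 2 arrays highest in liver genes, or without either array of nicotine 1.5. Each of these fits left 1 array at 1.5 mg/kg/day, so the spread at that dose was not measured. No difference between doses is read from them.

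A linear trend over the doses 0 to 4.5 mg/kg/day asked which genes followed the amount of nicotine. Pdk4 rose by 0.58 ± 0.05 log2 units per mg/kg/day (adjusted p = 0.0295), and Cdh1 fell by 0.65 ± 0.08 (adjusted p = 0.0475). The trend passed for 109 genes, 39 rising and 70 falling. Other rising slopes were those of Tob2, an antiproliferative factor, at 0.37 ± 0.04, Mief2 at 0.34 ± 0.04, Gabrr2, a GABA receptor subunit, at 0.31 ± 0.04, and Eda, ectodysplasin, at 0.25 ± 0.03. Falling slopes were those of Rbp2 at -1.31 ± 0.18, Ezr, which links membrane and actin in microvilli, at -0.56 ± 0.08, Cgn, of tight junctions, at -0.52 ± 0.07, and Pxylp1, an enzyme of proteoglycan synthesis, at -0.39 ± 0.05. The actin 3' to 5' ratio went down over the same doses, from 1.70 to 1.05, and visceral smooth muscle gene medians from 8.10 ± 0.24 (SD, n = 2) to 5.68 ± 0.11. The trend count became 0 without the saline arrays, without either saline array, and without nicotine 3.0 replicate 1 or nicotine 4.5 replicate 1, and 1 without nicotine 3.0 replicate 2. It became 1530 without both nicotine 1.5 arrays, 371 and 792 without replicates 1 and 2 of that dose, and 1 with array weights, an added constant of 64, no level filter or the mean of a gene's probe sets. With values as deposited 41 rose and 162 fell, and without nicotine 4.5 replicate 2 the balance turned over, with 102 rising and 48 falling.

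Any difference among the 4 groups passed the F test for 264 genes, which was 798 without the 2 arrays highest in liver genes, 458 without saline replicate 1, 494 without nicotine 1.5 replicate 2, 77 and 55 without the nicotine 3.0 arrays and 112 and 110 without the nicotine 4.5 arrays. The median fold change of all genes lay between 0.04 and 0.07 log2 units in the comparisons with saline.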

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

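The tests of lists between doses, and the limit of 1 log2 unit on the median difference, were chosen only after the results were seen. Of 96 such camera tests (32 lists in 3 comparisons), 32 had an adjusted p under 0.05 at the preset correlation, and the 7 with a median difference of at least 1 are given here because that test set them apart between dose groups. With an estimated correlation none of the 96 passed, and adjusted p = 0.879 for all 7. Adipocyte genes were higher at 3.0 than at 1.5 mg/kg/day by a median of 1.10 (19 of 19 genes in that direction, adjusted p = 2.80e-07). Cartilage genes were lower at 3.0 than at 1.5 by a median difference of -1.48 (20 of 22, adjusted p = 8.84e-04) and at 4.5 than at 1.5 by -1.58 (21 of 22, adjusted p = 6.18e-06). Keratinized epithelium genes differed by -1.43 between 3.0 and 1.5 (28 of 28, adjusted p = 2.06e-06) and by -1.04 between 4.5 and 1.5 (28 of 28, adjusted p = 1.95e-06). For cartilage and keratinized epithelium the level at 1.5 mg/kg/day came from replicate 1, whose list medians were 8.78 and 8.41, against 5.36 and 5.72 in replicate 2. Epithelial adhesion genes differed by -1.13 between 4.5 and 1.5 (27 of 27, adjusted p = 1.43e-11), with list medians of 7.45 and 6.27 in replicates 1 and 2 of 1.5 and of 5.27 and 5.90 at 4.5, so that replicate 1 of 1.5 added to this difference too. Glucocorticoid response genes were higher at 4.5 than at 3.0 by a median of 1.25 (17 of 18, adjusted p = 4.89e-15). Their list medians were 9.82 and 9.93 at 4.5 and 8.51 and 8.11 at 3.0, and 8.06 and 9.43 in replicates 1 and 2 of 1.5.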

How the results depend on the processing

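Leaving out both arrays of nicotine 1.5, and leaving out the 2 arrays highest in liver genes (saline replicate 2 and nicotine 1.5 replicate 2), were chosen only after the results were seen. Of 250 calls on named genes, 248 kept their direction under every alternative run and 55 also kept an adjusted p under 0.05 under all of them; the other 195 lost it under at least 1. Those kept throughout include Cym, Apoa4, Pga5, Bpifb1 and Muc5b at each dose, and Mymk, Ryr1, Chrnb1, Cidea, Nqo1 and Epcam for the mean of the doses. The 1380 genes for the mean of the doses became 618 with array weights and 844 with replicate number as a block, and ranged from 355 to 1491 when each array was left out in turn. The 337 genes at 1.5 mg/kg/day became 157 with an added constant of 1, 128 with array weights, 157 with the block, 15 with only the 4 arrays compared and 560 without the 2 arrays highest in liver genes (range without 1 array 103 to 912). The 506 genes at 3.0 became 278 with the block, 294 with 4 arrays and 896 without the 2 liver-rich arrays (52 to 995). The 934 genes at 4.5 became 441 with array weights, 522 with the block and 316 with 4 arrays (154 to 1368). The 264 genes of the F test became 139 with an added constant of 1, 147 with the block and 798 without the 2 liver-rich arrays (55 to 494). The trend, 109 genes, became 164 with an added constant of 1, 1 with 64, 203 with values as deposited, 242 with the filter at the 60th percentile, 1 each with no filter, the mean of a gene's probe sets, array weights, and trend and robust moderation, 0 each with the block, without the saline arrays and without the 2 liver-rich arrays, and 1530 without both nicotine 1.5 arrays (range 0 to 792). Between doses the count of 0 became 229 for 3.0 against 1.5 and 201 for 4.5 against 1.5 without the 2 liver-rich arrays (ranges without 1 array 0 to 47 and 0 to 39), and stayed 0 for 4.5 against 3.0 in every fit run. Shared genes between doses ranged from 50 to 659 for 1.5 and 3.0, 101 to 787 for 1.5 and 4.5 and 51 to 887 for 3.0 and 4.5. Of the 54 list calls, 0 were kept with an estimated correlation, and 39 (without saline replicate 2) to 54 under the other alternatives.

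Reversals were those of 2 lists and 2 genes. The list of collagen and matrix, nicotine 3.0 against saline, went from 0.45 to -0.0271 without the 2 liver-rich arrays, and ranged from -0.0284 to 0.91 when each array was left out. That of cartilage, nicotine 1.5 against saline, ranged from -0.0509 to 3.74 without 1 array. For endothelium, nicotine 1.5 against saline, the test turned down without nicotine 1.5 replicate 2 while the median stayed positive, at 0.0141 (adjusted p = 0.900). Ncam1, a neural adhesion molecule, went from -0.56 for the mean of the doses to 0.13 with the mean of its probe sets. Trbv1 at 4.5 went from 2.68 to -0.18 with an added constant of 1, where another probe set was chosen, and ranged from -0.28 to 2.82 without 1 array. For the counts and calls that moved, the cause was not tested. With values as deposited the share of changed genes that were higher fell in each comparison with saline, from 46.8% to 27.2% for the mean of the doses. A lone array left in a group is assumed to vary like the other groups. The replicate numbers did not pair the arrays: of 6 correlations between replicate differences of the groups, from -0.22 to 0.33, 1 exceeded 0.1. The dose as a rank was not run, since its equal steps give the trend already fitted. Signal over background limits what can be seen: 74.7% of genes with a probe set lay above the level filter, and with 2 arrays per group a 2-fold change in simulated data was recovered for 6.12% to 7.76% of genes in a dose comparison.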

Other observations

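The tests on organ markers, brown fat genes and Hox genes below were chosen only after the results were seen. In lists that did not pass as a whole, single genes changed with the mean of the doses. Not all of them are named here. Rises included those of Mmp13, a collagenase, at 2.27 ± 0.44 (SE), Mmp9 at 1.69 ± 0.31, Mmp2, a gelatinase, at 0.91 ± 0.21, and Ctsk, the protease of osteoclasts, at 1.78 ± 0.40 (adjusted p from 0.0237 to 0.0446). Per1, a clock gene also in the glucocorticoid list, at 1.37 ± 0.30, and Cry2, of the clock, at 0.99 ± 0.23, rose, and so did Nr4a1, an early response receptor, at 1.20 ± 0.15, Pkm, the pyruvate kinase of muscle, at 1.14 ± 0.16, and the growth factor receptor Fgfr1, at 1.12 ± 0.22. Falls included those of Ndrg1, a hypoxia-responsive gene, at -1.71 ± 0.19, Casp6, a caspase, at -1.17 ± 0.18, Bid, which promotes apoptosis, at -1.28 ± 0.26, and Fmo5, a monooxygenase of liver and intestine, at -2.93 ± 0.48.

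Of the 32 lists, 12 passed in none of the 4 comparisons with saline: apoptosis and p53, BMP and FGF signalling, circadian clock, erythroid, hypoxia and glycolysis, immediate early and heat shock, macrophage and immune, neutrophil and mast cell, osteoclast, Schwann cell and nerve, Wnt signalling and xenobiotic metabolism. Their adjusted p lay between 0.0636 and 0.977. In 14 of 128 list tests the median, the mean and the test differed in sign, and none of those 14 passed. Fry called 12 of the 128 as moving on balance in a single direction, and 86 as changed in either. Those 12 were nicotinic and cholinergic genes, oxidative stress and NRF2 targets, and salivary and mucous gland, in each of the 4 comparisons. The muscle lists were not among them.

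The 2 saline arrays were compared with the other 6 in a fit with a mean for each side, and so was every other choice of 2 arrays, 28 in all. The saline pair gave 1574 changed genes, and the highest count of any other pair was 9. Only 1 of the 28 choices reached that count, the saline pair itself, which argues against chance. It does not exclude chance, since 1 of 28 is the smallest share that 28 choices can give. In the other choices the difference of the saline arrays stayed in the spread, which keeps their counts low. What set the saline pair apart is not told by this test.

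Stomach and intestine genes were high in both saline arrays and near background in most nicotine arrays. Quantile normalization is argued against, since the median change of the 36 measured markers was -3.52 with the values as deposited and -3.44 after it. Tissue of the stomach and intestine in the saline samples stays open: 28 of the 36 markers were higher in both saline arrays than in all 6 nicotine arrays (3.57% for a single gene by chance), but on marker lists written after the values were seen this count repeats the pattern and does not decide it. A response to nicotine in a tissue of the same makeup follows the groups as well, but bears only on the lower levels in the nicotine arrays. The saline arrays had no nicotine, so their stomach medians of 7.86 and 7.66 are not a response to it. The 2 list medians differed by at most -0.27 between the 2 arrays of a nicotine dose. A like makeup is argued against by the saline arrays, whose medians differed by -1.93 for intestine, 3.45 for liver and 3.31 for kidney genes. Between these 2 arrays the other lists differed by at most -0.83, and stomach by -0.21. Guca2a was at 9.72 and 5.02 there, and Muc2 at 8.33 and 4.35 at nicotine 1.5. For the stomach genes, and for the intestine genes between groups, a response to nicotine cannot be told apart from tissue of these organs. For the liver genes, which were high in the saline arrays too, that response is argued against by a difference of 4.65 between the medians of the 2 arrays of nicotine 1.5.

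Brown fat genes were high at nicotine 3.0 and 4.5, and their median in nicotine 1.5 replicate 2, at 6.48, was like that in nicotine 4.5 replicate 2, at 6.44. Quantile normalization is argued against here too, with a median change of 1.72 for the values as deposited and 1.79 after it. A varying share of brown fat in the samples cannot be told apart from other explanations: Ucp1, Cidea, Cox7a1 and Otop1 differed between the 2 arrays of nicotine 4.5 by -5.24, -1.44, -0.91 and -2.42, a spread of 4.33 that goes against a fixed makeup in this pair, as Ucp1 went from an intensity of 4025 to 79.6 and Cidea, at most 71.8 in saline, from 2241 to 675, but these are 4 of the pattern's highest genes in 1 pair of arrays, which excludes nothing for the others. The nicotine dose alone also stays open, with a largest difference of 1.24 between the 2 arrays of a dose in the list's median, at nicotine 1.5. Single genes went against it, since Ucp1, Cox7a1 and Cidea differed by 4.27, 2.33 and 1.12 between the 2 arrays of nicotine 1.5 and Ucp1 by -5.24 at 4.5, but they were picked from the genes highest in the pattern.

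Some Hox genes of groups 9 to 13 were above the 60th percentile in every array, while genes patterning the face and jaws were near background. As a list, the Hox genes had medians of 5.36 to 6.08 in the saline arrays and nicotine 1.5 replicate 1, against 4.73 to 4.87 for the face and jaw genes. In the other arrays they were at 4.71 to 4.89 against 4.76 to 5.07, so the contrast of the lists was not seen there. Tissue of the trunk in every sample stays open: at least 2 of the 14 measured Hox genes lay above the 60th percentile in each array, with a highest count of 7, which repeats the pattern and does not decide it. Of the 12 measured Hox genes of groups 4 to 8, between 5 and 8 lay above that level in each array. That list, too, was written after values had been seen. Samples taken at differing body levels also stay open, with a difference of -3.04 in Hoxc10, a gene picked after its values were seen, between replicates 1 and 2 of nicotine 1.5. Weak probe sets of the face and jaw genes cannot be told apart from their absence, since no sample known to express them is among the 8 arrays; 5 of 12 exceeded the 60th percentile in at least 1 array. A response to nicotine stays open, not tested for the list: of its 8 genes above the level filter 1, Hoxd10, named after its values were seen, fell with the mean of the doses (-1.67, adjusted p = 0.0435), and the list medians averaged 5.72 in saline, 5.13 at nicotine 1.5, 4.73 at 3.0 and 4.84 at 4.5.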
